A study of Mus musculus with 20 samples.

How the data were processed

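Chromatin of KH2 ES cells and F9 cells was immunoprecipitated and sequenced, per the labels' protocols, with antibodies against V5, Oct4 and Sox17. ES cells received doxycycline at 1 µg/ml to induce a tagged Sox protein, and F9+RA cells 1 µM retinoic acid. The Sox2, Sox2KE and Sox17EK libraries of ES cells name the V5 antibody alone, the Sox17 libraries of ES cells name the Sox17 and V5 antibodies, and the Sox17 library of F9+RA cells names the Sox17 antibody. Oct4 libraries of ES cells name the Oct4 and V5 antibodies, those of F9 cells Oct4 alone. The labels do not say whether 2 named antibodies were used in turn, together or as alternatives. Of 20 samples, 18 had a peak list, and the 2 mock libraries were not analysed here.

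The deposited files hold 1 list per sample, with 5 columns and no header: chromosome, start, end, a peak name and a number. Peak names carry the MACS prefix, and the number was read as the authors' −log10 p-value on the scale that MACS writes (10 times −log10), because the lowest value of each list lies between 50 and 50.03. No label states this scale, so it is an inference from the values. The number, called a score in the text, was used to rank peaks within a list and is printed for named regions. Scores of different lists are not directly comparable, since depth was unknown. The highest scores of a list often share the value 3100. Start and end are positions in bp (another unit than a measurement), in build mm9 per the submitters' processing notes. Starts were taken to count from 0, as in a BED file, and are printed counting from 1. The aligner, the version and settings of the caller and its control library are not given in the sources used here. Depth was unknown, since only the length of a list is known.

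The lists give no summit, so the midpoint of the interval stood in for the summit named in the plan. N was the length of the shortest list, 5836, and the N strongest peaks of each list were compared. Peaks matched where midpoints lay within 200 bp, and peaks moved 10 kb to either side gave the background. For F9 cells N was 39768, the shortest of the 3 lists, and a site counted as absent where the whole other list had no match. Counting intervals are exact (Clopper-Pearson, 95%), and the interval of the odds ratio is the large-sample one on the log scale. The matching was tested on simulated lists made from the Sox2 ES replicate A list (5836 peaks): true overlaps of 10%, 20% and 40% came back as 10.1%, 20.1% and 40.1%. Simulated partners were moved by less than the matching distance, so this checks the counting only. Larger shifts of midpoints in wide peaks were not simulated. The permutation test called 2% of 1000 simulated comparisons without effect at a threshold of 0.05. Those simulated values were independent, whereas libraries of the same line may resemble each other, so the rate does not cover differences between lines.

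Libraries of 4 lysine and 4 glutamate Sox samples were compared by exact two-sided permutation tests of the difference of means, as were the 4 and 3 Oct4 libraries of ES lines. These 4 planned tests were adjusted together by the Benjamini-Hochberg method, and 7 tests over libraries added after the data were seen formed a separate family. Also added then were the classes of ES Sox sites, the comparison of chromosomes, and the sites of Sox17 without a V5-only peak. Nothing in the labels says that replicates A and B came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates of a protein come from 1 line, so residue and line cannot be separated beyond the 4 proteins.

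The groups, the 4 main tests and the changes of method first applied to them were fixed before the data were examined. The rule for named items took, for each comparison, the strongest peaks by mean rank that all libraries of one group share and no library of the other holds, up to 10. Lack of a peak there means neither a midpoint match nor an overlapping interval, so class sizes differ from those by midpoint. Positions are given in place of gene names, since the gene table used here belongs to build GRCm38 and the lists to mm9. For the same reason the planned motif search and the planned comparison with 7 fixed gene lists were not run. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.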

Results

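The series mapped, by chromatin immunoprecipitation and sequencing, where the HMG-box proteins Sox2 and Sox17 and the POU protein Oct4 (Pou5f1) bound in mouse cells of a pluripotent and of a primitive endoderm context. Sox2 and Oct4 are core regulators of pluripotent cells, and Sox17 is a marker and regulator of primitive endoderm. KH2 embryonic stem (ES) cells were induced with doxycycline to express a V5-tagged form of Sox2, Sox17, Sox2KE or Sox17EK. The mutants exchange a lysine and a glutamate that differ between Sox2 and Sox17, so that Sox2 and Sox17EK carry lysine and Sox2KE and Sox17 carry glutamate. F9 embryonal carcinoma cells were used untreated and after retinoic acid (RA), which turns them into primitive endoderm-like cells. Peak lists of 18 libraries were analysed. There were 8 Sox libraries of ES cells (2 per protein), 7 Oct4 libraries of the same lines (2 per line, 1 for the Sox17 line), and 1 library each of Oct4 in F9 cells, Oct4 in F9+RA cells and Sox17 in F9+RA cells.

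The lists held between 5836 peaks (Sox17 ES replicate B) and 84196 peaks (Oct4 F9+RA). Read depth was unknown, so the lists were compared at equal length, by their 5836 strongest peaks, with a match called where the midpoints of 2 peaks lay within 200 bp. Moving the peaks by 10 kb gave a background of 0.18% to 0.574% over all pairs of lists, with a median of 0.343%. Replicates of a group shared 65.8% of these peaks for Sox2, 55.5% for Sox17EK, 44.7% for Sox2KE and 36.4% for Sox17. The Oct4 replicates shared 42.7% in the Sox2 line, 54.3% in the Sox2KE line and 58.9% in the Sox17EK line. The median over the 7 groups was 54.3%, so a large part of any 2 lists differed even within a group. With all peaks Sox17EK was the lowest group, at 30.7%, below Sox17 at 35.6% and Sox2KE at 50.5%. Equal length did not mean equal strength. The 5836 peaks of Sox17 ES reached down to scores of 75.4 (A) and 50.03 (B, the whole list), against 127.7 to 974.7 in the other lists. Median widths were 970 and 873 bp for Sox17 and 312 to 680 bp for the other ES Sox lists. By interval overlap the Sox17 replicates shared 51.0%. Weaker and wider peaks may lower the shares counted for Sox17.

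**Figure D1:**
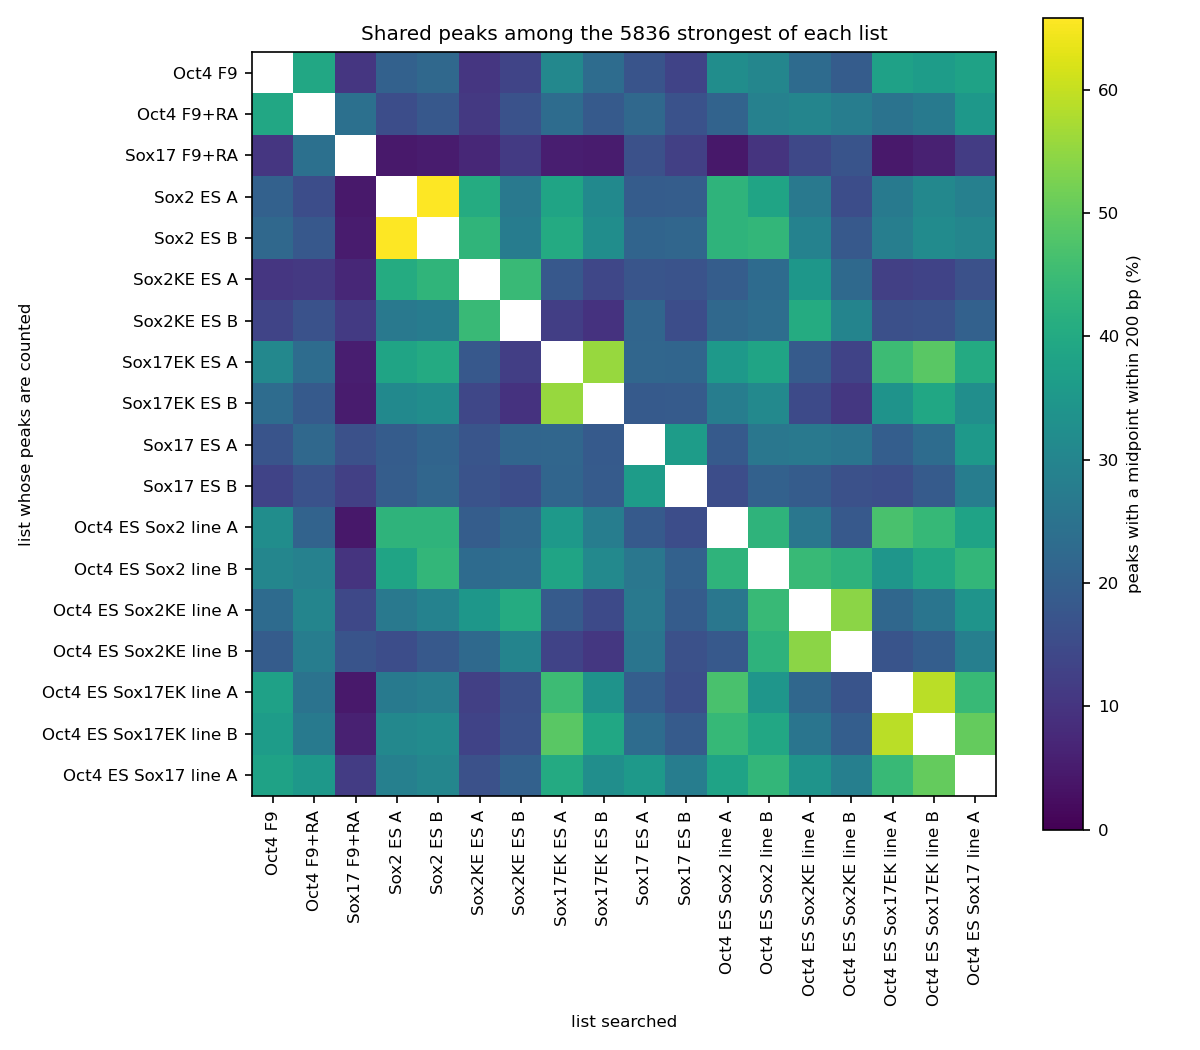
Each cell gives the percentage of the 5836 strongest peaks of the row's list with a peak of the column's list within 200 bp, for the 18 lists. The brightest pair is Sox2 replicates A and B at 65.8%, and the Sox17 F9+RA row is dark for the Sox2 and Sox17EK libraries of ES cells.

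Oct4 was found at more of the peaks of the lysine proteins than of the glutamate proteins in ES cells. In their own lines, 41.9% ± 1.85 of Sox2 peaks and 41.8% ± 7.34 of Sox17EK peaks had an Oct4 peak, against 31.8% ± 4.53 for Sox2KE and 31.6% ± 5.29 for Sox17 (SD, n = 2 each). A lysine-bound region on chromosome 14, at 67381473 to 67382044, had peaks of Sox2 (authors' scores 1324 and 1056) and of Sox17EK (831 and 841) and no overlapping peak in any Sox2KE or Sox17 library. Oct4 peaks lay there in the Sox2 line (3100 and 2406), in the Sox17EK line (1986 and 1337) and in the Sox17 line (1333), and in neither Oct4 library of the Sox2KE line. Another such region, on chromosome 8 at 12698411 to 12699422, had Sox17EK peaks of 2565 and 1118 and Sox2 peaks of 788 and 521. Over the 4 lysine and 4 glutamate libraries the shares were 41.8% ± 4.37 and 31.7% ± 4.02 (SD), a difference of 10.1 percentage points, with every lysine library above every glutamate library. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 libraries can give, and 0.0571 after Benjamini-Hochberg adjustment over the 4 planned tests, so the result fails the correction. The order turned with all peaks in use, the glutamate lists then being higher by 2.83 points in lists of unequal length (lysine minus glutamate -2.83, exact permutation p = 0.743), and with whole Oct4 lists the difference was 4.81 points (exact permutation p = 0.4).

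Endogenous Sox17 sites of F9+RA cells were met most often by Sox17 in ES cells, and by Sox2KE more often than by Sox2 or Sox17EK. Of the 5836 strongest Sox17 F9+RA peaks, 14.5% ± 2.67 had a peak of Sox17 in ES cells and 9.18% ± 2.73 a peak of Sox2KE, against 4.69% ± 0.4 for Sox2 and 5.30% ± 0.279 for Sox17EK (SD, n = 2 each). On chromosome 11, at 43290720 to 43291951, Sox17 peaks scored 3100 and 1312 in ES cells and 3100 in F9+RA cells. No Sox2, Sox2KE or Sox17EK library had a peak there. The Oct4 score at this region was 3100 in the Sox17 line, 2290 in F9+RA cells and 355 in F9 cells, and 61.8 in the only other ES library with a peak. On chromosome 8, at 129139296 to 129140463, Sox17 scored 1765 and 1270 in ES cells and 2612 in F9+RA cells, with an Oct4 score of 3122 in F9+RA and 143 in F9 cells. A region bound by both glutamate proteins and by no lysine library lay on chromosome 5 at 120029669 to 120030777. Its Sox2KE scores were 719 and 1897. The Sox17 scores in ES cells were 93.5 and 99.4, above the medians of those lists (82.2 and 73.1). The Sox17 F9+RA score was 1375 and the Oct4 F9+RA score 2246.

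The glutamate libraries together shared 11.8% ± 3.76 and the lysine libraries 4.99% ± 0.454 of the Sox17 F9+RA peaks (SD, n = 4 each), a difference of 6.82 points with all glutamate libraries above all lysine libraries. The exact two-sided permutation p was 0.0286, again the smallest possible, and 0.0571 after adjustment over the 4 planned tests. With all peaks the difference was 4.01 points (exact permutation p = 0.514). At the level of the 4 proteins, 2 against 2 cannot give a p below 0.333, and the 2 libraries of a protein share its line.

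**Figure D2:**
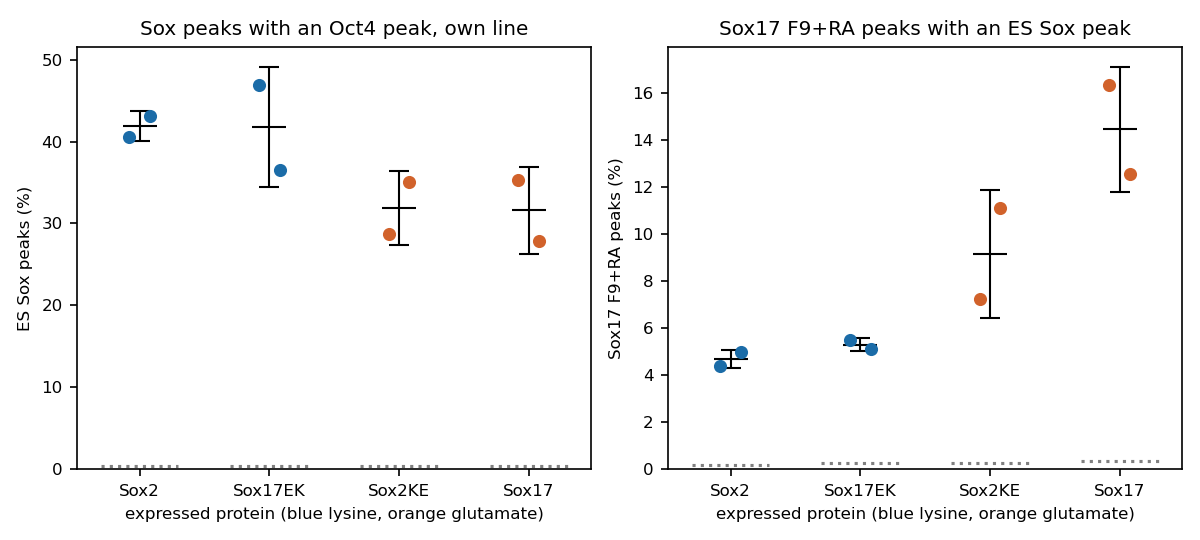
Left, the percentage of the 5836 strongest Sox peaks of each ES library with an Oct4 peak of the same line, and right, the percentage of Sox17 F9+RA peaks with a peak of each ES Sox library; points are libraries, bars the mean and SD (n = 2), dotted lines the background of peaks moved by 10 kb. Lysine libraries lie above glutamate libraries on the left and below them on the right.

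Whether a mutant's sites moved from those of its own wild type towards those of the other was asked by pairwise sharing. Sox17EK shared 35.5% ± 4.42 of its peaks with Sox2 and 20.2% ± 1.66 with Sox17, its own wild type (SD over 4 pairs of libraries). Sox2KE shared 34.5% ± 8.52 with Sox2, its own wild type, and 17.8% ± 2.57 with Sox17. Sox2 and Sox17 shared 20.3% ± 1.29, and the 2 mutants 13.5% ± 3.52. The lysine form of Sox17 thus lay nearer to Sox2 than to Sox17 by 15.3 points, while the glutamate form of Sox2 remained nearer to Sox2 than to Sox17 by 16.6 points (8.66 without Sox2KE replicate A and 24.6 without replicate B). With all peaks the first difference was smaller, at 8.09 points. The Sox17 libraries name the Sox17 antibody beside V5 and the other Sox libraries name V5 alone. In every pair with Sox17, antibody and protein therefore cannot be told apart. No test was run on these pairs, which reuse libraries. The low replicate overlap of 36.4% for Sox17 may lower what other lists share with it. These pairs were not compared by interval overlap. As a percentage of the geometric mean of the 2 replicate overlaps, Sox17EK reached 58.7% with Sox2 and 44.9% with Sox17. Sox2KE reached 63.6% with Sox2 and 44.2% with Sox17, so both orders held.

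Oct4 sites of F9+RA cells differed in part from those of untreated F9 cells, and Sox17 lay at more of the sites found only after RA than of those found only before. Among the 39768 strongest peaks of each Oct4 list, 15816 of F9+RA cells had no midpoint match in F9 cells (RA-only) and 13684 of F9 cells had none in F9+RA cells (F9-only). A Sox17 peak lay at 28.3% of the RA-only sites (exact 95% interval 27.6 to 29.0), at 27.4% of the 23952 sites in both (26.8 to 27.9) and at 10.1% of the F9-only sites (9.62 to 10.6). Backgrounds were 2.84%, 1.93% and 2.19%. The odds ratio of RA-only against F9-only sites was 3.51 (95% interval 3.29 to 3.75, Fisher's exact test, p too small to be represented). F9-only sites were chosen to lack an Oct4 peak in F9+RA cells, the cells of the Sox17 list. That choice by itself may lower their Sox17 share. Sites in both had nearly the share of RA-only sites and a higher fold over background (14.2 against 9.99). The contrast thus went with presence in the Oct4 F9+RA list and does not show a gain of Sox17 sites with RA. The strongest RA-only regions with Sox17 were on chromosome 3 at 121642616 to 121643598 (Oct4 F9+RA score 3100, Sox17 1993), on chromosome 4 at 111155453 to 111156628 (3100 and 2758) and on chromosome 1 at 167784582 to 167785450 (3122 and 1177). In ES cells the chromosome 1 region had Sox17 scores of 1821 and 879 and an Oct4 score of 1686 in the Sox17 line, and no peak in any other ES library. The strongest F9-only region, on chromosome 8 at 114312829 to 114314179, had an F9 score of 1009.

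Midpoints shift within wide peaks, and the class sizes depended on them. With overlap of intervals by at least 1 bp as the match, 7816 RA-only and 6541 F9-only sites remained, and the Sox17 share then differed by 29.5 points instead of 18.2. The difference was 10.7 points with midpoints within 100 bp and 7.69 with all peaks. Among the 1000 strongest peaks it was 28.1, but by overlap of intervals that set holds no F9-only site. Of the 1000 strongest Oct4 peaks of F9 cells, 366 had no midpoint match but 0 lacked an overlapping peak in F9+RA cells, while 41 of the 1000 strongest of F9+RA cells lacked one in F9 cells. The F9+RA list is the longer, with 84196 against 64582 peaks, which by itself leaves fewer F9 peaks without a partner. From the side of Sox17, 36.9% of its 39768 peaks had an Oct4 peak of F9+RA cells (exact 95% interval 36.4 to 37.4) and 23.8% one of F9 cells (23.4 to 24.3). With 1 library per condition and no replicate, these intervals and tests compare the libraries, not the conditions, and cover counting error only.

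**Figure D3:**
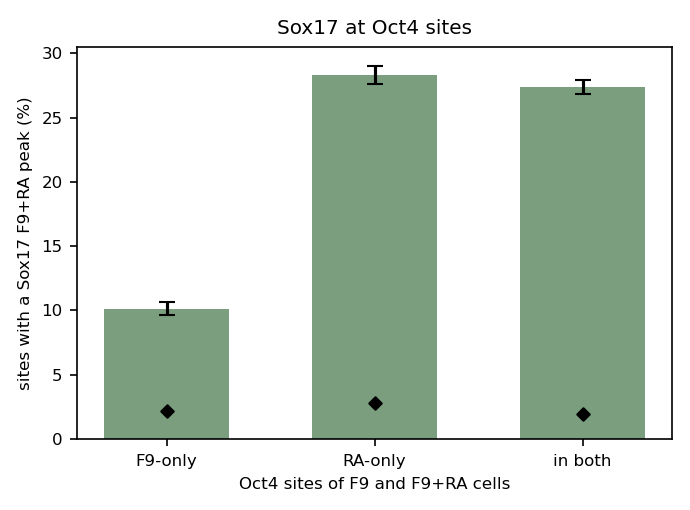
Bars give the percentage of RA-only, F9-only and shared Oct4 sites with a Sox17 F9+RA peak, with exact 95% intervals, and diamonds the background of peaks moved by 10 kb. F9-only sites are at 10.1% and the other classes at 28.3% and 27.4%.

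Oct4 sites of the ES lines were compared with those of F9 and F9+RA cells to ask whether they moved with the Sox protein expressed. Peaks shared with Oct4 of F9 cells made up 34.1% ± 3.52 in the 4 Oct4 libraries of lysine lines and 26.7% ± 9.88 in the 3 of glutamate lines (SD), a difference not detected by the exact two-sided permutation test (p = 0.286, adjusted p = 0.286). Peaks shared with Oct4 of F9+RA cells made up 25.5% ± 3.46 and 31.0% ± 3.62 (exact permutation p = 0.114, adjusted p = 0.152). Single libraries moved the first difference of 7.43 points to 3.71 (without Oct4 Sox2KE line B) or 13.0 (without Oct4 Sox17 line A). The exact permutation p of the latter was 0.0667, the smallest that the remaining libraries can give. The second difference of -5.50 became -3.49 without Oct4 Sox17 line A. With all peaks the first difference reversed to -0.872 (exact permutation p = 0.886) and the second was -7.26 (exact permutation p = 0.2). Among the 1000 strongest peaks the second was -2.08 (exact permutation p = 0.571). The Sox17 line was apart from the Sox2KE line in the first measure, at 37.9% against 22.9% and 19.2%. In a comparison added after the data were seen, peaks shared with Sox17 of F9+RA cells made up 14.4% ± 2.66 in glutamate lines (11.74% to 17.05%) and 6.23% ± 2.57 in lysine lines (4.30% to 9.89%). The sets did not overlap, and the difference of 8.14 points was not past 0.05 (exact two-sided permutation p = 0.0571, adjusted 0.0667 over 7 added tests), and with all peaks it was 5.14 (exact permutation p = 0.114).

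Measures added after the data were seen compared Sox peaks with the Oct4 lists of all lines. Sox peaks of every one of the 8 libraries met Oct4 most often in their own line, on average 36.8% against 23.5% in the other lines, an excess of 13.3 points. Of the 24 ways to assign Oct4 lines to Sox proteins, the true one gave the largest excess and the next 7.41 (exact one-sided permutation p = 0.0417, the smallest possible; 0.0667 adjusted over 7 added tests). At 56 of the strongest Sox17 F9+RA sites, both Sox17 ES libraries and no V5-only Sox library had a peak. Oct4 of the Sox17 line lay at 48 of these 56 sites (85.7%, exact 95% interval 73.8 to 93.6), and the highest of the 6 other Oct4 ES libraries at 16 (28.6%, 17.3 to 42.2). Oct4 of F9+RA cells also lay at 48 (85.7%) and Oct4 of untreated F9 cells at 25 (44.6%, 31.3 to 58.5). The sites were chosen to lack Sox peaks in the other 3 lines, which lowers the Oct4 shares of those lines in advance. Labels of the Oct4 libraries of ES cells name a V5 antibody beside the Oct4 antibody, so that peaks of the tagged Sox protein in them cannot be set apart from peaks of Oct4.

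Merging the strongest peaks of the 8 ES Sox libraries gave 23796 sites. All 4 lysine libraries and no glutamate library had a peak at 956 of them, all glutamate and no lysine libraries at 85, and both Sox2 forms without either Sox17 form at 1814. Presence and absence were read from whole lists, which held 10301 and 5836 peaks for Sox17 and 23924 to 71693 for the other proteins. Shorter Sox17 lists leave fewer sites with a Sox17 peak, so the sizes of these classes are not directly comparable. These counts depend strongly on the settings: they were 470, 31 and 508 where only the strongest peaks counted as bound, and the glutamate-only sites rose to 248 without Sox2KE replicate A and 220 without Sox17 replicate B. Intervals over sites cover counting error only. A Sox17 F9+RA peak lay at 34 of the 85 glutamate-only sites (40%, exact 95% interval 29.5 to 51.2) and at 3.14% of lysine-only sites (30 of 956, 2.13 to 4.45). The share was also 39.8% at the 658 sites held by all 8 libraries (36.1 to 43.7) and 12 of 30 at sites of both Sox17 forms alone, so it was not peculiar to glutamate-only sites, which hold a Sox17 ES peak by definition. Oct4 F9 peaks lay at 44.7% of glutamate-only (33.9 to 55.9) and 74.8% of lysine-only sites (71.9 to 77.5). Lysine-only sites had an Oct4 peak in 80.0% and 90.6% of cases in the Sox2 line, 75.6% and 85.6% in the Sox17EK line and 77.8% in the Sox17 line, against 38.2% and 21.0% in the Sox2KE line. Sites of the Sox2 forms had Oct4 at 76.6% ± 14.5 in the lines of those forms (n = 4) and at 20.9% ± 8.25 in the lines of the Sox17 forms (n = 3, SD). Sites of each class were chosen by the Sox peaks of the same lines, and Sox libraries match the Oct4 list of their own line best. The choice of sites thus favoured the direction of this contrast, and the 2 cannot be told apart. It need not fix that direction, since the lysine-only sites, chosen to lack Sox17 peaks, had the 77.8% in the Sox17 line.

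**Figure D4:**
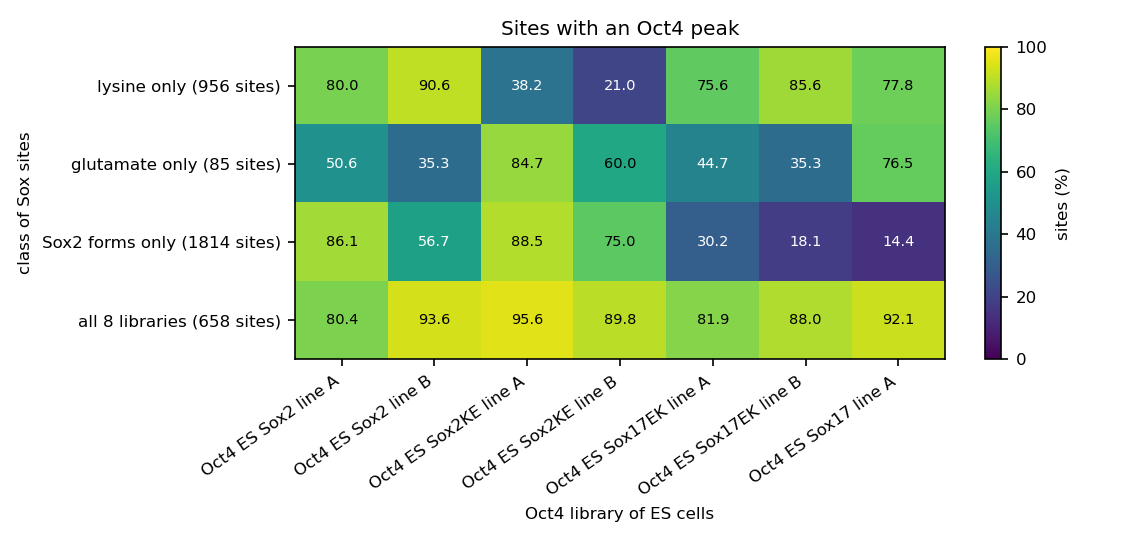
Each cell gives the percentage of a class of Sox sites (rows) with an Oct4 peak in a given Oct4 library of ES cells (columns). Lysine-only sites have Oct4 at 75.6% to 90.6% except in the Sox2KE line, and sites of the Sox2 forms have it mostly in the lines of those forms.

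The lists of the 2 cell lines also differed in how their peaks were spread over chromosomes, a comparison added after the data were seen. Chromosome 1 held 11.0% ± 0.895 (SD, n = 15) of the strongest peaks in ES libraries and 3.80% in the 3 F9 libraries, a ratio of 2.90, and chromosome 14 held 6.36% ± 0.563 and 2.44%, a ratio of 2.60. Chromosomes 4, 6, 12 and X held smaller shares in ES libraries, with ratios of 0.733, 0.698, 0.419 and 0.426. For these 6 of 20 chromosomes the exact two-sided permutation p was 0.00123, the smallest that 15 against 3 libraries can give, and 0.00408 after Benjamini-Hochberg adjustment over the chromosomes. Libraries of a cell line share its genome, so they are not independent samples, and these p-values compare the libraries of 2 cell lines only.

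**Figure D5:**
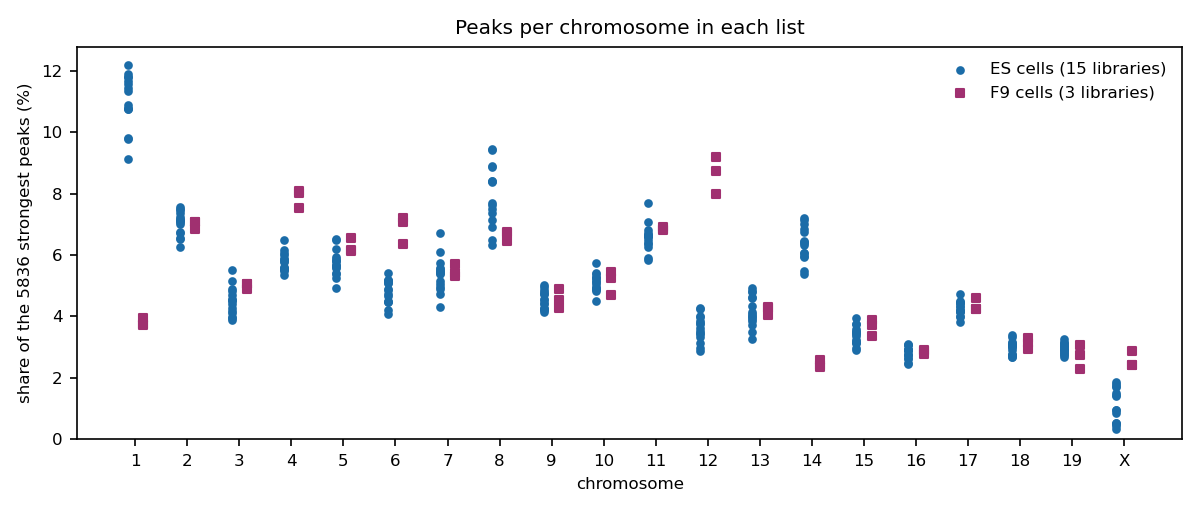
Points give the share of the 5836 strongest peaks of each list on each chromosome, for the 15 ES libraries (circles) and the 3 F9 libraries (squares). On chromosomes 1 and 14 all ES libraries lie above all F9 libraries, and on chromosomes 4, 6, 12 and X below them.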

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

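The tests of Oct4 libraries, of the V5 and Sox17 antibodies, of peaks found in both replicates and of sites without Oct4 F9 peaks, and the comparison of chromosomes, were chosen after the data were seen.

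The lysine minus glutamate difference in the share of Oct4 ES peaks that also lay in the Oct4 F9 list differed between the Sox forms. It was 10.1 points between the Sox2 and Sox2KE lines and -0.857 between the Sox17EK and Sox17 lines, which differ by 11.0 points. Each pair of libraries had the sign of its form. The 37.9% of the Sox17 line was close to the 37.7% and 36.3% of the Sox17EK line, though, so -0.857 shows no clear difference. The difference was not tested, and the Sox17 line has 1 library. None of the 10 sets of 4 libraries searched had a library far from the rest.

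The higher Oct4 share at lysine than at glutamate peaks was set against 3 technical explanations, and none was excluded. The Sox17 antibody named for the Sox17 libraries was not among them. Sox2KE, named for V5 alone, had a share near that of Sox17 (31.8% and 31.6%). Poorer Oct4 libraries of the glutamate lines stay open: at the 658 sites of all 8 Sox libraries their strongest Oct4 peaks covered 52.9% ± 18.6 against 56.8% ± 4.73 for lysine lines (glutamate minus lysine -3.86 points, within the SD), with 52.0% and 34.8% in the Sox2KE line but 72.0% in the Sox17 line. Whole Oct4 lists went the other way, with 95.6%, 89.8% and 92.1% in glutamate and 80.4% to 93.6% in lysine lines. A V5 signal in the Oct4 ES libraries cannot be told apart either, since the lists named for Oct4 alone differ: lysine exceeded glutamate libraries by 10.6 points against Oct4 F9, with no overlap of the sets, and by 2.27 points against Oct4 F9+RA, where they overlapped (exact permutation p = 0.4). Less reproducible glutamate lists cannot be told apart from the residue: among peaks found in both replicates the difference was 8.85 points (exact permutation p = 0.0286) and every lysine library lay above every glutamate library, as the criterion written before asked. The lowest lysine and the highest glutamate library were only 0.126 points apart, though, with Sox2 at 51.4% and Sox17 at 50.7%. That such a gap must exceed the counting error was required only after the value was seen. The residue itself stays open as well.

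The sharing of Sox17 F9+RA sites with the glutamate proteins was set against sites called in most libraries and against a shared antibody. Without the sites of the Oct4 F9 list the difference was 4.69 points, with 5.77% to 9.60% for glutamate and at most 3.06% for lysine libraries. For Sox2KE, whose labels name V5 alone, the lower library still exceeded the highest lysine library by 1.75 points. The value for Sox2KE argues against the antibody for that protein. Leaving out sites of the Oct4 F9 list cannot decide on sites called in most libraries. Both sets lost matches with those sites. The mean share went from 11.8% to 7.71% of the 3397 sites left for glutamate libraries, and from 4.99% to 3.02% for lysine libraries. Presence in the Oct4 F9 list does not measure how many libraries hold a site, though. Sites called in most libraries therefore stay open as a cause. For the Sox17 libraries a signal of the Sox17 antibody cannot be told apart from bound Sox17. At sites of both Sox17 libraries without a V5-only peak, the Oct4 share of the Sox17 line was 57.1 points above the next line's, but leaving out sites with Sox peaks in the other lines lowers their Oct4 shares in advance. A residue effect on the choice of sites stays open as well.

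Peaks of ES and F9 libraries were spread differently over chromosomes (816 ways to choose 3 of 18 libraries, ratios of 2.90 and 2.60 for chromosomes 1 and 14). In whole lists 97.0% of the 10 Mb bins of these chromosomes (32 of 33) had the larger ES share. A different copy number of whole chromosomes in the 2 cell lines would give this. Both chromosomes were chosen for their larger ES shares, so the bins show only that the excess was spread along them. Chromosomes 4, 6 and X were not divided into bins. No biological explanation was tested. Chromosome 12 differed only in part: ES over F9 ratios from 80 to 120 Mb were 0.504, 0.218, 0.184 and 0.222, and 7 of its 13 bins had a larger ES share.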

How the results depend on the processing

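Alternatives for the own-line excess, for ES Oct4 peaks shared with Sox17 F9+RA, for classes of sites and for similarity without single libraries, and those without single Oct4 libraries, with peaks in both replicates and without Oct4 F9 sites, were chosen after seeing the data. The cause of the changes was not tested. With all peaks, the Oct4 co-occupancy difference reversed to -2.83 points, the share with Oct4 F9 among ES Oct4 libraries reversed to -0.872, the Sox17 F9+RA difference was 4.01 (no longer past 0.05), and Sox17EK to Sox2 minus to Sox17 was 8.09. With whole Oct4 lists co-occupancy was 4.81 and with 100 bp 8.03, neither past 0.05. Leaving out single libraries gave 7.23 to 13.0 for co-occupancy, 5.31 to 8.35 for Sox17 F9+RA, 3.71 to 13.0 and -6.99 to -3.49 for ES Oct4 peaks shared with Oct4 F9 and F9+RA, 6.80 to 9.46 for those shared with Sox17 F9+RA (3.33 with the 1000 strongest peaks, there past 0.05), with every direction kept. The p of co-occupancy then rose above 0.05 without Sox2KE A or B, Sox17EK A, Sox17 A or B, Oct4 Sox2KE line B or Oct4 Sox17EK line B. For Sox17 F9+RA the p did so without each of the lysine libraries in turn. Leaving out Oct4 Sox17 line A left the Sox17 libraries without a co-occupancy value. The exact permutation p was then 0.0667, the smallest that the remaining libraries can give. The median replicate overlap was 42.8% at 100 bp and 65.3% by interval overlap. Lysine-only, glutamate-only and Sox2-form-only sites numbered 470, 31 and 508 where only the strongest peaks counted, and at 100 bp 42 and 1190 for the latter 2. Without single libraries they ranged from 1008 to 1322, from 91 to 248 (248 without Sox2KE A, 220 without Sox17 B, 148 without Sox17 A) and from 1871 to 2468. Site counts of RA-only and F9-only Oct4 sites were 48712 and 29120 with all peaks and 405 and 366 with the 1000 strongest, and Sox17 remained more frequent at RA-only sites in 3 alternatives (7.69, 10.7 and 29.5 points). The 1000 strongest peaks (28.1 points) decide nothing, since 0 of their F9-only sites lack an overlapping F9+RA peak. The own-line excess stayed between 9.82 and 17.2 in 18 alternatives. As replicate block, only the Oct4 library of the same letter was used, which left Sox17 B without a value and gave 9.39 points for co-occupancy (exact permutation p = 0.0286). Same-letter pairs shared 39.1% and other pairs 37.8%, so the letters were treated as names only. Ranking by another strength column, the motif search and the gene lists were not run. Unknown depth limits every comparison of list length.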

Other observations

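All tests in this part were chosen after the data were seen.

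Chromosome X held 1.62% of the strongest peaks in the 4 lysine Sox libraries (1.41% to 1.85%) and 0.591% in the 4 glutamate libraries (0.480% to 0.840%), a difference of 1.03 points (exact two-sided permutation p = 0.0286, adjusted 0.0667 over 7 added tests). In whole lists the means were 1.43% and 1.04%. Chromosome X was not alone in this: on chromosomes 2, 3, 8, 10 and 18 the 2 sets of Sox libraries did not overlap either. On chromosome 8 the order was the opposite, with 6.32% to 7.13% in lysine and 7.69% to 9.44% in glutamate libraries. The adjustment over the added tests does not cover the choice of chromosome X among all chromosomes. The Oct4 libraries had 1.70% and 0.960% in the Sox2 line, 1.71% and 1.51% in the Sox17EK line, 0.411% and 0.326% in the Sox2KE line and 0.942% in the Sox17 line.

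The lysine and glutamate split of the 8 ES Sox libraries gave 1041 sites held by all libraries of one side and none of the other. Presence was read from whole lists of unequal length. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave as many, the other being the one between Sox2 forms and Sox17 forms, with 1844 sites. However, 32 splits part the replicates of a protein, which by itself keeps their counts low (at most 195). The third split that keeps replicates together, Sox2 with Sox17 against both mutants, gave 55, and 3 splits are too few for a share under 0.05.

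The strongest Sox2KE region without a Sox2 peak but with a Sox17 F9+RA peak and no Oct4 F9 peak among the named regions was on chromosome 3 at 121271974 to 121273246. Its Sox2KE scores were 518 and 2994, the Oct4 scores of the Sox2KE line 955 and 362, and the Sox17 F9+RA score 899. This region was singled out after its values were seen.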
